A study of Manihot esculenta with 2 samples.

How the data were processed

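Poly(A)-enriched RNA from shoots of cassava (Manihot esculenta, cultivar TM12) was sequenced as native RNA on an Oxford Nanopore instrument with the SQK-RNA002 kit, per the labels' protocols. In this assay each strand of RNA is read directly, starting at its poly(A) tail, so that a read keeps its strand and its 3′ end while its 5′ end can be lost. Seedlings were 2 weeks old and had been grown in 16 h of light at 20 °C and 8 h of dark at 18 °C. They were either left untreated or kept at 4 °C in the light for 3 h before harvest. There was 1 library per group and there were no replicates.

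The authors deposited 1 table of aligned reads per library. Reads were aligned with minimap2, per the submitters' processing notes. The version of the aligner, the genome build and any filter on reads are not given in the sources used here. Each line of the deposited tables holds the first and last aligned base of 1 read, its strand, and the number, lengths and offsets of its aligned blocks. The values are positions on 18 chromosomes named LG1 to LG18, and the gaps between blocks are taken as introns. Every read name occurred once in its table. The score column was empty in all 8872911 untreated and 554789 cold lines, so that reads with several equally good positions could not be set aside. Loci with near-identical copies elsewhere are therefore uncertain, and their reads can have been divided between copies.

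The gene table at hand, of assembly M.esculenta_v8, was not used to name loci. On 18 of the 18 chromosomes the last aligned base lay before the last gene of that table, so the coordinates belong to another build. Coordinates below are 1-based and as the deposited tables give them. The 31 gene lists fixed in advance, and the shares of unannotated and antisense reads, need gene names or an annotation of the same build and were not analysed here.

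The design had provided for clusters of reads in place of genes if there were no annotation, and this was followed. On each strand, bases covered by at least 5 reads of both libraries together formed stretches. Stretches were split where the coverage fell below 5% of the peaks on both sides. They were joined into a locus where at least 5 spliced reads, and at least 5% of the reads at the lower peak, linked them over a gap of at most 20000 nt. Each read was given to the same-strand locus that held most of its aligned bases. A locus is a read cluster and can hold part of a gene or neighbouring genes. These thresholds, like the definition of introns below, were set after the tables had been opened and before any ratio was computed.

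Read counts per locus were made from the deposited read positions and scaled to CPM, the count per 1000000 reads assigned to loci in that library. A locus entered the comparison when the mean of its 2 CPM values equalled at least 10 reads in the shallower library. It was called higher or lower in cold when the CPM ratio, cold over untreated, was at least 2 or at most 0.5 and its 95% interval left out 1. The intervals are exact conditional binomial (Clopper-Pearson) intervals. They cover counting error only, and say nothing about the spread between plants. A count of 0 was replaced by 3 reads, which makes the ratio a bound. One read was worth 0.113 CPM in the untreated and 1.81 CPM in the cold library, and 3 reads were worth 0.339 and 5.43 CPM. No p-value was computed between the libraries. Named loci are the 12 higher and the 12 lower loci whose interval bound nearest to 1 lay farthest from 1, and for introns and read ends the 5 with the largest difference by the nearest bounds. This rule, the size rules and most alternatives were fixed before the data were examined.

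An intron was listed when at least 5 reads spliced it, with splice sites within 10 nt taken as 1, and when at least 5% of its spanning reads in a library did so. A read counted as unspliced when 1 block covered the intron and 10 nt on each side. The spanning reads of an intron are those that spliced it or left it unspliced. As an addition made after seeing the data, unspliced reads were also set against all reads that reached 10 nt past the intron on both sides, however they were spliced there. Introns with at least 10 spanning reads in each library were compared, and were called more or less retained when the shares differed by at least 20 percentage points and the exact binomial 95% intervals did not overlap. For the number of introns in a locus, only introns spliced by at least 50% of the spanning reads and by at least 20% of all reads over them were counted, and overlapping introns counted once. Read 3′ ends were compared by their medians in loci with at least 20 reads in each library, with 200 bootstrap draws of each median, taken through the distribution of its rank. In the same loci a read was taken to reach the 5′ end when it started within 50 nt of the upstream 5% point of all read starts, with both libraries weighted equally. That point stands in for the annotated 5′ end that the design named. Lists of loci were set against 10000 random lists matched on mean CPM in 10 classes, and for neighbouring loci also on 5 classes of CPM, 5 of covered length and on having introns.

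The steps were tested on simulated data. For the CPM comparison, which ran on 10849 entering loci, 200 loci were changed, 100 up and 100 down. At 4-fold, 99 of the raised and 62 of the lowered loci were called, and at 8-fold 100 and 63. None was called in the wrong direction, and 106 and 90 unchanged loci were called in these simulations. A lowered locus can fall below the entry rule, which sees the mean of both CPM values, so the calls recover raised loci more fully than lowered ones. With 200 of 39799 introns raised by 50 percentage points, 198 were called, as were 9 unchanged introns. With 200 of 6291 loci shifted by 300 nt at the 3′ end, 200 were called and 0 unchanged loci. The simulated ends had a standard deviation of 50 nt, small against the shift of 300 nt, so this recovery was largely set by the simulation. It does not give the rate of calls among unshifted real ends. Draws of real untreated reads at the cold number gave 14 to 32 downstream and 20 to 33 upstream shifts of at least 100 nt.

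Alternatives covered the scaling, the entry rule, strand, the overlap rule, thinning of the untreated library to the cold depth, the fold, and the thresholds for introns and ends. Other locus settings, a restriction to reads of 500 to 1000 nt and the removal of a length trend were added after seeing the data. Calculations used Python 3.11.15 with NumPy 2.4.6 and SciPy 1.17.1, and plots Matplotlib 3.10.9.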

Results

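The data set compared the transcripts of untreated cassava shoots with those of shoots kept at 4 °C for 3 h, by direct sequencing of native poly(A) RNA. Cassava is a tropical root crop. The untreated library held 8872911 aligned reads and the cold library 554789, a 16.0-fold difference in depth. Of these, 8854755 (99.8%) and 552994 (99.7%) were assigned to 29978 read clusters, here called loci, 14955 on the plus and 15023 on the minus strand. Of the loci, 10849 were read deeply enough to be compared, and these held 90.5% of the untreated and 90.8% of the cold assigned reads. Each group was 1 library without replicates, so every difference below is one between these libraries, and the intervals cover counting error only.

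The first comparison asked which loci differed in abundance after 3 h of cold. In the cold library 611 loci (5.63%) were higher and 448 (4.13%) were lower by the 2-fold rule. Large differences were few, with 45 loci at least 4-fold higher and 59 at least 4-fold lower, and 10 and 14 at 8-fold. The most marked group was formed by 3 adjacent single-exon loci on the minus strand of chromosome LG2, all of them 18.0-fold to 24.3-fold higher.

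These 3 loci lay between positions 11252396 and 11259215 and were separated by 1814 and 1260 nt. The first, at 11252396 to 11253682, went from 56 reads (6.32 CPM) to 63 reads (114 CPM), a ratio of 18.0 (95% interval 12.4 to 26.3). The second, at 11255496 to 11256763, went from 79 reads (8.92 CPM) to 120 reads (217 CPM), a ratio of 24.3 (18.2 to 32.7). With the untreated library thinned to the cold depth it had 1 untreated read, and its log2 ratio went from 4.60 to 6.91. The third, at 11258023 to 11259215, went from 22 to 27 reads and had a ratio of 19.7 (10.8 to 36.2). Whether reads were divided between similar copies within this group was not tested.

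The largest ratio belonged to a locus with 1 intron on LG8, at 30844497 to 30845470 on the minus strand. It had 7 untreated and 24 cold reads, 0.791 against 43.4 CPM, and a ratio of 54.9 (23.0 to 151). With the untreated library thinned to the cold depth it had 0 untreated reads, and its log2 ratio, 5.78 with all reads, was then at least 3. The most abundant of the named higher loci lay on LG15 at 2496250 to 2497336, on the minus strand with 2 introns. It had 510 untreated and 524 cold reads, or 57.6 and 948 CPM, and a ratio of 16.5 (14.5 to 18.6). A locus with 10 introns on LG10, at 2067593 to 2073777 on the minus strand, was 15.6-fold higher (9.91 to 24.6). Loci on LG14 at 13529396 to 13530655, on LG18 at 705460 to 709787 and on LG9 at 9305983 to 9307378 were 12.8-fold, 12.2-fold and 9.27-fold higher. The other 3 named loci, on LG1 at 31921656 and 32891494 and on LG12 at 29198896, had ratios of 6.45, 7.64 and 6.24. With reads of 500 to 1000 nt alone the log2 ratio went from 3.97 to 5.15 at 2067593 on LG10 and from 2.64 to 2.01 at 29198896 on LG12, and with thinning from 3.68 to 2.81 at 13529396 on LG14.

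Among the lower loci, that on LG2 at 9022815 to 9024090, on the minus strand with 3 introns, fell furthest by its interval. It went from 519 CPM (4600 reads) to 36.2 CPM (20 reads) and was 14.4-fold lower, with a ratio of 0.0696 (0.0425 to 0.108). A locus on LG3 at 22110850 to 22114050, on the plus strand, went from 696 to 61.5 CPM and was 11.3-fold lower. A locus on LG15 at 5510719 to 5513626 was the most abundant of the named lower loci and went from 916 to 143 CPM, 6.41-fold lower. A locus on LG2 at 2198508 to 2200631 had 347 untreated reads and 0 cold reads, and was at least 7.22-fold lower with 3 reads in place of 0, while the bound of its 95% interval was 5.84-fold. It was the only compared locus without a cold read, and none lacked untreated reads. Loci on LG11 at 24741673 and on LG1 at 24531820 had 1 cold read each, with ratios of 0.0353 (0.000893 to 0.198) and 0.0408 (0.00103 to 0.229). The other 6 named loci, on LG1, LG5, LG12, LG14 and LG15, were 7.40-fold to 10.3-fold lower. With reads of 500 to 1000 nt alone, 4 of the 12 had values over 2 times nearer to 1, on 0 to 4 cold reads, and those with 0 are bounds. These were the loci at 24741673 on LG11 (log2 ratio -4.82 to at most -1.30), 2198508 on LG2 (at most -2.85 to at most -1.26), 11366255 on LG15 (-3.17 to -1.58) and 2117801 on LG1 (-3.36 to -2.04).

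**Figure D1:**
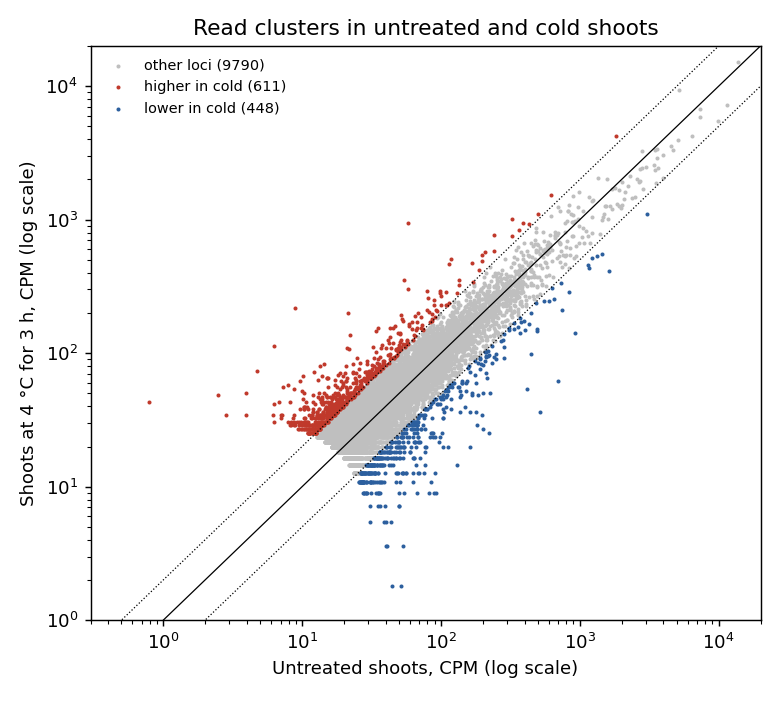
Each point is 1 of the 10849 compared loci, with CPM in untreated shoots on the x axis and CPM after 3 h at 4 °C on the y axis, both on log scales. The solid line marks equal values and the dotted lines a ratio of 2 and of 0.5. The 611 loci called higher are red and the 448 called lower are blue, and the 1 locus with 0 cold reads is drawn at 3 reads.

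With cold reads drawn at random from the untreated shares, 20 draws called on average 26.1 loci higher and 34.7 lower, and at most 44 and 50. The balance between higher and lower loci depended on the scaling, and in simulated data the calls recovered raised loci more fully than lowered ones. The median log2 ratio of the compared loci was 0.15, and with that median set to 0, which divides each ratio by 1.11, 387 loci were higher and 659 lower. The share of higher loci among the called ones was 57.7% with the total as the scale and 37.0% with the median.

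The called loci differed in the number of introns seen in their reads, in classes chosen after the ratios had been seen. A locus that holds part of a gene can lack introns that the gene has. Loci without introns were called lower more often than higher, and loci with many introns higher more often than lower, although most loci of either kind passed neither rule. Of 921 intronless loci, 151 (16.4%, exact 95% interval 14.1 to 18.9) were lower and 44 (4.78%) were higher. Of 1916 loci with 11 or more introns, 15 (0.783%, 0.439 to 1.29) were lower and 156 (8.14%) were higher. Intronless loci made up 33.7% of the lower loci (29.3 to 38.3), 7.20% of the higher loci (5.28 to 9.55) and 8.49% of all compared loci.

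The median log2 ratio was -0.31 (-0.37 to -0.26) in intronless loci and -0.12 (-0.15 to -0.08) in those with 1 intron. It was -0.01 with 2 or 3 introns, 0.17 with 4 to 6, 0.30 with 7 to 10 and 0.42 (0.39 to 0.44) with 11 or more. Of 10000 random lists matched on mean CPM, 0 had a lower median than the intronless loci, and 10000 had a lower one than the loci with 11 or more introns. Relative to the median of all loci these values were -0.47 and 0.26, and the loci with 2 or 3 introns then lay at -0.16. With the trend of the ratio with covered length removed, the median was -0.22 in intronless loci and 0.11 in loci with 11 or more introns. Spliced loci alone went from a median of -0.08 in the shortest 20% of the loci to 0.36 in the longest 20%. Examples among the intronless loci are the 3 higher loci on LG2, and the lower loci on LG15 at 11366255 to 11369191 (130 to 14.5 CPM, less far with reads of 500 to 1000 nt as given above) and LG14 at 2832347 to 2833320 (161 to 19.9 CPM). Of the loci with 11 or more introns, that on LG15 at 9769081 to 9773460 was 5.92-fold higher and that on LG16 at 28666803 to 28671563 was 5.22-fold higher.

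Intronless loci were also short, with a median covered length of 1277 nt against 4001 nt in loci with 11 or more introns. Covered length counts every covered base of a locus, with introns that unspliced reads covered, and is not transcript length. Within the shortest 20% of the loci, of up to 1637 nt, the median log2 ratio was -0.39 (-0.46 to -0.35) in 607 intronless loci and -0.08 (-0.10 to -0.05) in 1563 spliced loci. In that class 20.4% of the intronless and 5.18% of the spliced loci were lower in cold. From 1638 to 2291 nt these shares were 8.94% of 179 intronless and 4.27% of 1989 spliced loci, with medians of -0.20 and 0.10. From 2292 to 2957 nt they were 11.2% of 89 and 2.45% of 2082, with medians of -0.16 and 0.19. Longer intronless loci were few. From 2958 to 3889 nt, 2.56% of 39 intronless and 2.44% of 2130 spliced loci were lower, with medians of 0.03 (-0.26 to 0.19) and 0.25. From 3890 nt, 0 of 7 intronless and 1.29% of 2164 spliced loci were lower. There the intronless median, 0.53 (-0.10 to 1.77), lay above the spliced one, 0.36.

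**Figure D2:**
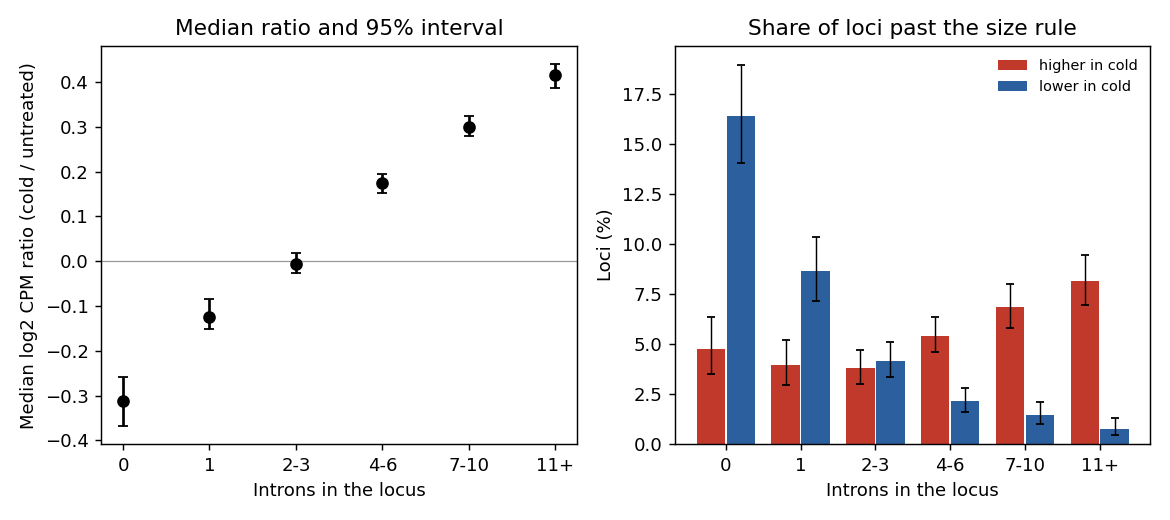
The left panel plots the median log2 CPM ratio, cold over untreated, for 6 classes of loci by their number of introns, with 95% order-statistic intervals as bars. The right panel plots the percentage of each class called higher (red) and lower (blue), with exact binomial 95% intervals. The median goes from -0.31 without introns to 0.42 with 11 or more, while the share of lower loci goes from 16.4% to 0.783%.

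The second comparison concerned the reads themselves, since the completeness of native RNA reads describes the RNA and the library. The median aligned length was 721 nt in the untreated and 810 nt in the cold library, a difference of 89 nt. Reads of at least 1000 nt made up 29.7% and 37.1%. Spliced reads made up 64.2% of the untreated and 70.5% of the cold reads. Within 6291 loci with at least 20 reads in each library, the median read was longer in cold in 66.7% (exact 95% interval 65.5 to 67.8), by a median of 24.5 nt (22 to 27.5). In these loci 39.7% of the untreated and 39.8% of the cold reads reached the 5′ end, a difference of 0.180 percentage points (0.0308 to 0.330). As a mean over loci the shares were 28.7% and 30.7%, a difference of 1.99 points. Among reads of at least 200 nt the pooled difference was 0.000136 points (-0.151 to 0.151), while the mean over loci was 29.2% and 31.1%, a difference of 1.92 points. The size of the difference thus depended on the weighting of loci, and the pooled value also on the shortest reads.

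The third comparison asked whether introns were retained to another extent in the cold. Retention is the share of unspliced reads among those that spliced the intron or left it unspliced, and reads that spliced another intron over the same bases were left out. It was low in both libraries, with a mean over 40584 introns in 8534 loci of 3.68% in untreated and 3.55% in cold shoots. Pooled over these introns it was 2.63% and 2.44%, a difference of -0.187 percentage points (-0.214 to -0.159). More retention in cold was found for 48 introns in 43 loci and less for 26 introns in 21 loci. With cold reads drawn from the untreated shares, 20 draws gave at most 14 and 3 such introns, and on average 10.05 and 1.6. The rule thus called more introns as more retained than as less retained even without a change. The order of the counts turned under settings that left few introns called. With the untreated library thinned to the cold depth 4 introns were more and 6 less retained, and with at least 30 spanning reads 3 and 7. With reads of 500 to 1000 nt they were 2 and 4, and the cause of the turn was not told apart. As a share of all reads over the intron, a measure added after seeing the data, 47 introns were more and 16 less retained, 45 and 14 of them by both measures.

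The clearest changes lay in a locus on LG17, at 24267869 to 24272074 on the plus strand, whose abundance had a ratio of 0.365 (0.336 to 0.395). Its intron at 24268315 to 24268437 was unspliced in 5170 of 14139 untreated reads over it (36.6%, exact 95% interval 35.8 to 37.4) and in 25 of 253 cold reads (9.88%, 6.50 to 14.2). Among the 6405 and 104 reads that spliced this intron or left it unspliced, the retention was 80.7% and 24.0%. An overlapping intron with the same end, beginning at 24268185, went from 35.7% to 9.72% of all reads over it and in retention from 39.0% to 13.9%. It contains the first intron, and a read unspliced over it is unspliced over both, so their changes are not separate. Of the reads spliced at their shared end, 86.2% of 8956 untreated and 65.4% of 228 cold reads used the longer intron. More retention was seen on LG18 at 3346220 to 3346307, from 9.57% (18 of 188 reads) to 48.6% (17 of 35 reads), with the same shares among all reads over it. In a locus on LG11 at 1408701 to 1411391, 3 introns were retained in 3.93% to 9.31% of the untreated and in 36.8% to 50% of the cold reads, with 10 to 23 cold reads each. That locus had 28 cold reads in all, so the 3 introns share reads and are not separate changes.

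The other 4 of the 10 named introns met the rule only without the reads spliced otherwise. On LG18 the intron at 4606024 to 4606875 had a retention of 67.6% in untreated and 21.2% in cold shoots, but was unspliced in 12.4% (10.8 to 14.1) and 7.37% (4.09 to 12.1) of all reads over it. For that on LG16 at 3471021 to 3471542 the retention was 99.2% and 65%, and the shares of all reads were 8.69% (7.66 to 9.82) and 3.29% (1.76 to 5.56). In the LG17 locus an intron of 42 nt at 24269312 to 24269353 lies within that at 24268813 to 24269444, so that their changes are not separate. Their retention went from 94.4% to 46.2% and from 52.9% to 87.0%, while their shares of all reads went from 58.6% (54.7 to 62.4) to 44% (35.1 to 53.2) and from 51.5% (47.2 to 55.7) to 40.8% (31.0 to 51.2). With introns of at least 60 nt alone, 48 were more and 25 less retained.

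The fourth comparison concerned the position of read 3′ ends, which mark the poly(A) site. In most loci the ends did not move: of 6291 loci, 79.4% had medians within 10 nt of each other, and the median shift was 1 nt. In 79 loci the cold median lay at least 100 nt downstream and in 18 at least 100 nt upstream. In 20 draws of the cold number of reads from the untreated reads, 14 to 32 loci shifted downstream (mean 23.4) and 20 to 33 upstream (mean 26.4). When the bootstrap interval also had to leave out 0, a condition chosen after seeing the data, 31 loci shifted downstream and 1 upstream. By the most used end in place of the median, an alternative fixed beforehand, the directions were less unequal. There 154 loci shifted downstream and 88 upstream, and no draws were made for this measure.

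The largest shift, of 2032 nt, was on LG16 at 24760532 to 24763004 on the minus strand, where 10 of the 43 cold reads with downstream ends began before the untreated median end. In the other 4 named loci most such reads did so. On LG14 at 10669244 to 10671519 the shift was 748 nt (720 to 827), and 20 of 25 such reads crossed. On LG8 at 327215 to 330234 it was 381 nt (374 to 385), with 27 of 28 reads crossing. On LG6 at 25508661 to 25511338 and on LG4 at 26820642 to 26824738 it was 258 nt each, with 17 of 18 and 39 of 42 reads crossing.

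**Figure D3:**
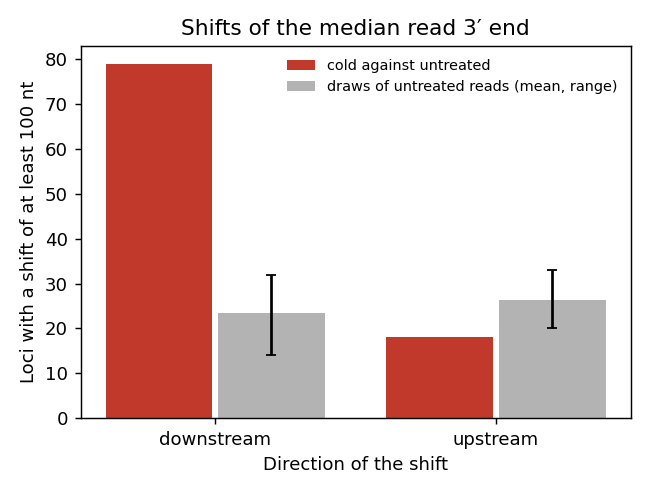
Bars count the loci whose median read 3′ end differed by at least 100 nt, by direction, for cold against untreated reads (red) and as the mean of 20 draws of untreated reads (grey, with the range as error bars). The observed 79 downstream shifts lie above the range of the draws, 14 to 32, and the 18 upstream shifts lie below theirs, 20 to 33.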

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

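The 24 named loci kept their direction under the 6 alternatives run for them. They had been chosen for interval bounds far from 1, which made this likely. Of 144 values, 131 stayed within the counting interval. Of the 13 others, several moved far, on few reads. With thinning the log2 ratio at 30844497 on LG8 went from 5.78 to at least 3 (0 untreated reads), at 11255496 on LG2 from 4.60 to 6.91 (1 untreated read) and at 13529396 on LG14 from 3.68 to 2.81. With reads of 500 to 1000 nt it went from -4.82 to -1.30 at 24741673 on LG11 and from -2.85 to -1.26 at 2198508 on LG2, both with 0 cold reads and so bounds. It went from -3.17 to -1.58 at 11366255 on LG15, from -3.36 to -2.04 at 2117801 on LG1, from 3.97 to 5.15 at 2067593 on LG10 and from 2.64 to 2.01 at 29198896 on LG12. The other 4 moved by at most 1.41 times. The length trend, read length, locus settings, interval condition, span limit, share of all reads over an intron and alternatives for structure classes were chosen after seeing the data. For the number of loci called, 288 (148 higher, 140 lower) were called with an entry rule of 30 reads, 104 (45 and 59) at 4-fold and 510 (313 and 197) with reads of 500 to 1000 nt, where fewer reads or a stricter rule leave fewer calls. Without an entry rule there were 1863 (1136 and 727). With the median log ratio set to 0 there were 387 higher and 659 lower, and with the length trend removed 363 and 486. Without the 100 most-read loci in the total there were 501 higher and 523 lower. Counts stayed within 1.5 times with that scaling, without strand, under the overlap rule, with thinning and under the other locus settings. Thinning gave 684 higher and 464 lower loci, of which 376 and 315 were also called with all reads.

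The median log2 ratio of intronless loci was -0.47 with the median set to 0, -0.37 without the 100 most-read loci in the total, -0.22 with the length trend removed and -0.23 with reads of 500 to 1000 nt. That of loci with 11 or more introns was 0.26, 0.35, 0.11 and 0.49 in the same order, and 0.38 with an entry rule of 30 reads. Intronless loci made up 40% of the lower loci with that rule and 23.5% with the length trend removed. The difference in reads reaching the 5′ end was 0.000136 points (-0.151 to 0.151) among reads of at least 200 nt and 1.99 points as a mean over loci, and 1.92 points with both.

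Of introns, 10 differed with at least 30 spanning reads (3 more, 7 less retained), 125 at 10 points (83 and 42), 10 with thinning (4 and 6) and 6 with reads of 500 to 1000 nt (2 and 4). As a share of all reads over the intron 63 differed (47 and 16), where reads spliced otherwise enter the share. Of 3′ ends, 256 shifted by at least 50 nt (217 downstream, 39 upstream), 17 with at least 50 reads (15 and 2), 242 by the most used end (154 and 88) and 32 with an interval that left out 0 (31 and 1). Where a threshold or the number of reads does not account for a change, the cause was not tested. The cold depth, at which 1 read is 1.81 CPM, limits all counts. Alternatives by mapping quality were not run, since the score column was empty, and counting every line could not differ, since each read occurred once. The alternatives for gene lists and for unannotated reads were not run.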

Other observations

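Except for the counts with thinning, with the median log ratio set to 0 and without the 100 most-read loci in the total, the tests and tallies in this part were chosen after the tables had been opened, and 1 test, that of reads cut short at the 3′ end, was set only after its result had been seen. Some of the 448 loci lower in cold lay next to each other, more often than in random lists, though most had no lower neighbour. Neighbouring loci can be parts of 1 gene or near-identical copies, which was not tested. Of 3921 pairs of neighbouring compared loci on 1 strand, at most 20000 nt apart, 18 pairs were both lower, against a mean of 6.61 in 10000 random lists matched on mean CPM, of which 0 reached 18. Of these pairs 11 had an intronless member, and in 10000 lists matched on CPM, covered length and on having introns the mean was 7.46, with 2 lists that reached 18. The pairs formed 16 separate groups, against a mean of 7.27 in those lists, of which 22 reached 16. Both members were higher in 17 pairs, against a mean of 12.3 in either kind of list, and 1158 and 1172 of the lists reached that number. On LG18, 4 neighbouring loci on the minus strand between 3107041 and 3117641 were lower, with ratios of 0.489, 0.486, 0.191 and 0.101. On LG14, intronless loci at 2824599 and 2832347 had ratios of 0.222 and 0.123. On LG14, loci at 369341 and 373768 were 7.32-fold and 3.69-fold higher.

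The 20 most abundant loci took 10.9% of the untreated and 9.44% of the cold assigned reads, and 16 of them had a ratio below 1. The only one called was on LG4 at 22107905 to 22110217, which went from 1824 to 4210 CPM. Of 61 pairs of compared loci that overlapped by at least 100 nt on opposite strands, 46 had no called member and 14 had 1. The remaining pair was called lower on both strands, on LG2 at 8566317 and 8566073. That 0 pairs were called in opposite directions says little with so few called members. Among splice sites used by several introns, the choice of partner differed at 20 of 3318 sites that shared the first base and at 7 of 3185 that shared the last. On LG18 at 4604481 to 4610021, the intron from 4606024 to 4606172 took 93.8% of 1494 untreated and 73.7% of 198 cold reads at its first base. It lies within the intron from 4606024 to 4606875, whose retention and share of all reads are given with the introns. No count by chance was made for these splice sites.

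The over-representation of intronless loci among the lower loci was weighed against 3 technical explanations. Genomic DNA in the untreated library is argued against, because unspliced reads on the opposite strand of the 151 loci amounted to 0.207% of the reads on their own strand. A trend with covered length, which stood in for transcript length, is argued against as the whole cause as well. Covered length can exceed transcript length where unspliced reads cover introns, and transcript length itself was not measured. With the trend with covered length removed, intronless loci were still 2.76 times as frequent among the lower loci as among all loci. They were then also more frequent among the higher loci, at 14.3% (10.9 to 18.4) against 8.49% of all loci, but less so than among the lower loci, at 23.5% (19.8 to 27.5). With reads of 500 to 1000 nt alone the lower loci held 3.44 times the share of all loci. The pattern thus did not need reads outside that range. The range can hold different parts of the reads of short and of long loci, so read length stays open as part of the cause. With it the median log2 ratio was -0.23 in intronless loci and 0.49 in loci with 11 or more introns. An effect of the cold was not tested, and other differences between the libraries stay open.

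The longer reads of the cold library were weighed against a library-wide difference in RNA integrity or read recovery and against a shift towards loci with longer transcripts. Among 2750 loci with a CPM ratio of at least 0.8 and at most the inverse of that, 68.9% had a longer median read in cold, which a library-wide difference would give. The share of reads that reached the 5′ end was only 0.180 percentage points higher in cold when pooled, and 1.99 points as a mean over loci. A difference in RNA integrity is thus not settled. By the bounds of 20 and 40 nt set beforehand the shift between loci was not decided, since the median difference within loci, 24.5 nt, lay between them. Weighting the untreated reads to the cold shares of the loci moved their median by 42 nt, from 722 to 764 nt. This left 46 nt to the 810 nt in cold. The changed shares of loci thus account for part of the difference, and what changed the shares was not tested. The cold and the library cannot be separated here, and no biological explanation was tested.

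The downstream shift of read 3′ ends was weighed against 3 technical explanations. Too few cold reads are argued against, because draws of untreated reads gave on average 23.4 downstream shifts against the 79 observed. Neighbouring genes joined in 1 locus are argued against as a general cause: in 70 of the 79 loci, or 88.6% (exact 95% interval 79.5 to 94.7), at least 50% of the cold reads with downstream ends crossed the untreated median end. The other 9 loci, with that on LG16 that shifted by 2032 nt among them, stay open to it. Reads cut short in most loci of the untreated library are argued against, since the median shift was 1 nt. That value cannot exclude reads cut short in some loci, or in a minority of the reads of a locus. Its bound was also set after the result had been seen. No biological explanation was tested.

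Altogether 13 explanations for 6 patterns were written down, 7 of them before any ratio was seen and 6 for the patterns of intronless lower loci and of 3′ ends, after these had been noticed. Of these, 11 were tested. The 2 others concerned an excess of intronless loci among the higher loci, which was not seen in the main comparison (7.20% against 8.49% of all loci), and they were not tested for the 14.3% found with the length trend removed. For the unequal numbers of higher and lower loci, the depth gap is argued against, since thinning left 1.47 times as many higher as lower loci. The calling rule itself stays open as a cause, and was not among the explanations written down. In simulated data with 100 loci raised and 100 lowered 4-fold, it called 99 and 62. Thinning keeps that rule and cannot remove this inequality. A scale set by a few abundant loci stays open. The quotient was 0.587 with the median log ratio set to 0, but that setting moves all loci alike. Without the 100 most-read loci in the total, 501 loci were higher and 523 lower, while the median log2 ratio of the compared loci went from 0.15 only to 0.09. For the unequal numbers of introns more and less retained, the longer cold reads stay open. The quotient was 0.5 among reads of 500 to 1000 nt, on 6 introns, but that setting left 8355 of 40584 introns. Thinning alone also turned the order, to 4 more and 6 less retained. The calling rule stays open as a cause for introns too, and was not among the explanations written down. Draws of cold reads from the untreated shares, which hold no change, called on average 10.05 introns more and 1.6 less retained.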
